A study of Rattus norvegicus with 16 samples.

How the data were processed

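Total RNA from 20 mg of soleus muscle of each of 16 female rats was labelled with biotin and hybridised to Affymetrix rat whole-genome expression arrays, 1 array per rat, per the labels. The labels state that RNA was checked by electrophoresis and that only samples without signs of degradation were used. Training ran on 5 days per week for 8 weeks, 1.5 hours per session at an incline of 25 degrees, with intervals at 85 to 90% of maximal oxygen uptake, and tissue was taken 48 hours after the last session, per the labels' protocols. The 4 groups of 4 rats were HCR sedentary, HCR trained, LCR sedentary and LCR trained. The labels describe the samples as separate rats, so the p-values rest on the spread between animals within groups, which the fitted model pooled over the 4 groups.

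The values were the authors' deposited log2 expression values per probe set. RMA, which corrects background, normalizes probes by quantiles and summarises each probe set, and limma are named in the submitters' processing notes, with versions not given in the sources used here. The range and the near-equal array medians, 5.90 to 5.98, fitted log2 values from RMA. Whether all 16 arrays were summarised together was not given in the sources used here. Scan dates were not used here, so batches of scanning were not tested. Because RMA removes a shift common to all probe sets, differences are relative to the bulk of the array. Summaries give signal without detection calls, so no floor of detection was set, and the number of arrays limits the precision.

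Of 31042 probe sets tested, 20826 had 1 gene symbol, 436 had several and 9780 had none in the platform annotation, and none was named from a probe set with several symbols. Current entries by gene identifier in the RefSeq table of assembly GRCr8 were found for 20758 probe sets, and 0 symbols changed. The table was used for names alone. A gene could have several probe sets, and the text gives how many called genes had other probe sets of opposite sign for training in HCR and for trained lines, and names those among the genes it names.

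Before the data were examined, the groups, the tests, the gene lists, the rule for naming genes and most alternative settings were fixed. The model was fitted with limma 3.58.1 in R 4.3.3, with 4 group means over all 16 arrays, 12 residual degrees of freedom and empirical Bayes moderation without trend, and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. Comparisons were HCR against LCR in sedentary and in trained rats, trained against sedentary in each line, the interaction, and the 2 effects averaged over the other factor. Comparisons share groups: both comparisons with HCR trained rats use the same 4 arrays, so their calls are not independent, and overlaps between them are not reported.

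The 29 gene lists covered fatty acid oxidation, fatty acid uptake, the citric acid cycle, the respiratory chain, mitochondrial and cytosolic ribosomes, the proteasome, mitochondrial biogenesis regulators, glycolysis, slow and fast fibre genes, endothelial genes, extracellular matrix, antioxidant defence, heat shock genes, protein breakdown, the circadian clock, immediate early genes, calcium handling, insulin signalling, amino acid breakdown, MHC genes, and markers of adipocytes, blood cells, macrophages and leukocytes, Schwann cells, smooth muscle, satellite cells and proliferation. Each list used the brightest probe set of each gene and needed at least 5 measured members. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. With fry 0 lists passed in any comparison, and the smallest adjusted p was 0.0768, between trained rats. In every list that passed, the median, the mean and the test had the same sign. Some genes stood in more than 1 list. Two-sided exact permutation tests over all splits of 4 against 4 arrays were used for list means per array and control measures.

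The text names genes by this rule. Probe sets with 1 symbol and a mean in the brighter group at or above the 40th percentile of all probe sets (5.61) qualified, with 1 probe set per gene, that of smallest p. Named were the 12 largest rises and 12 largest falls that passed in each comparison, the 5 of smallest p in each direction where under 10 genes passed, members of the lists, and 16 key genes. Probe sets without a symbol that are named were chosen after their values were seen, as were the genes shown for the array HCR trained 3.

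Control measures per array were the 3' minus the middle probe set of the beta-actin controls, the 3' minus the 5' probe set of the GAPDH controls, and the mean of the polyadenylated spike-in controls. They were tested over 100000 permutations for correlation with the first component. The beta-actin index depends on actin expression as well as on RNA and labelling.

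Alternative settings fixed at that point were a fit on the 8 arrays of the groups compared, leaving out probe sets below the 40th percentile, quantile normalization of the deposited values, median centring, a variance trend with robust moderation, array weights, the replicate number as a block, 1 probe set per gene, a fold threshold of 1.5, an estimated correlation and leaving out each array. Chosen after seeing the data were leaving out HCR sedentary 2 and HCR trained 3 together, the beta-actin or the GAPDH index as a covariate, both arrays left out with the beta-actin index, list means per array, the list test on the interaction, list medians without each array and without both HCR sedentary 2 and HCR trained 3, and the fast fibre mean without HCR trained 3. Such medians are given where they turned or moved by over 1.5 times, at their extremes where several arrays did so. The tests were first run on simulated data with 31042 probe sets. For trained HCR against trained LCR, 84% of 100 probe sets changed by 1 log2 unit and 99% of 100 changed by 2 were recovered, with 6 false calls. For trained against sedentary HCR the shares were 86% and 99%, with 10 false calls, and the 2 unchanged comparisons gave 0 calls. The simulated noise was normal and independent between probe sets, without the structure that the real arrays share. These shares and false calls therefore check the code and do not give the power or error in the real data.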

Results

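Gene expression was profiled in soleus muscle, a predominantly slow-twitch postural muscle, from 16 female rats of 2 lines bred by artificial selection on treadmill running. HCR denotes the line selected for high running capacity and LCR the line selected for low capacity, both at generation 16 of selection. In each line 4 rats ran intervals on a treadmill for 8 weeks and 4 stayed sedentary, and all were killed at about 7 months, 48 hours after the last session in the trained groups. Each array held 1 rat, so n = 4 rats per group throughout, and the number of arrays limited the precision. After 57 control probe sets were left out, 31042 probe sets were tested. Pairs of arrays correlated between 0.941 and 0.996 across probe sets, and no pair was identical. The questions the design poses are how the lines differ with and without training, how each line's muscle responds to training, and whether the responses differ.

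Slow and fast fibre transcripts set 1 array apart. On the array HCR trained 3, Myh4, the type IIB fast myosin heavy chain, read 13.57 on the log2 scale against 8.43 to 11.08 on the other 3 HCR trained arrays. On the same array Tnnt1, slow troponin T, read 10.19 against 13.58 to 13.92, and Lpl, lipoprotein lipase, read 10.52 against 12.78 to 12.81. The array HCR sedentary 2 had the highest mean of the collagen and other extracellular matrix genes, at 1.74 log2 units above the average over all arrays, and the highest mean of the macrophage and leukocyte markers, at 1.21. The first principal component held 32.0% of the variance and over all arrays did not separate the lines (two-sided exact permutation p = 0.208) or the training states (exact p = 0.459). In trained rats alone its scores did not overlap, at 13.7 to 43.9 in HCR and -36.0 to -6.77 in LCR (exact permutation p = 0.0286, adjusted 0.190 over 20 tests). The second held 18.2% and gave exact p = 0.904 for line and 0.799 for training. The third, which was not planned as a test, held 15.1% and gave exact p = 0.0272 for line, which was 0.163 after adjustment over 6 tests.

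A control measure of the arrays moved with the first component. The beta-actin control index, the signal of the 3' probe set minus that of the middle probe set, was 1.90 ± 0.35 (SD, n = 4) in HCR trained rats, 1.27 ± 0.14 in LCR trained, 1.18 ± 0.54 in HCR sedentary and 1.65 ± 0.32 in LCR sedentary. The trained groups did not overlap (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow, adjusted 0.190 over 20 tests). Across the 16 arrays the index correlated with the first component at Pearson's r = 0.918 (permutation p = 1e-05, the smallest the resamples can give, adjusted 3e-05 over 3 indices) and Spearman's rho = 0.871 (p = 3e-05, adjusted 9e-05). Without the 2 arrays farthest from the median index r was 0.902, and within the groups it was 0.897. The GAPDH control index gave r = 0.599 (permutation p = 0.00192, adjusted 0.00288), rho = 0.591 (p = 0.0182, adjusted 0.0182), r = 0.481 without the 2 farthest arrays and 0.446 within the groups. The mean of the polyadenylated spike-in controls gave r = 0.647 (permutation p = 0.00667, adjusted 0.00667), rho = 0.679 (p = 0.00493, adjusted 0.00739), r = 0.617 without the 2 farthest arrays and 0.367 within the groups. The spike-in mean was 7.23 ± 0.26 in HCR trained and 6.74 ± 0.11 in LCR trained rats (exact permutation p = 0.0286, adjusted 0.190).

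**Figure D1:**
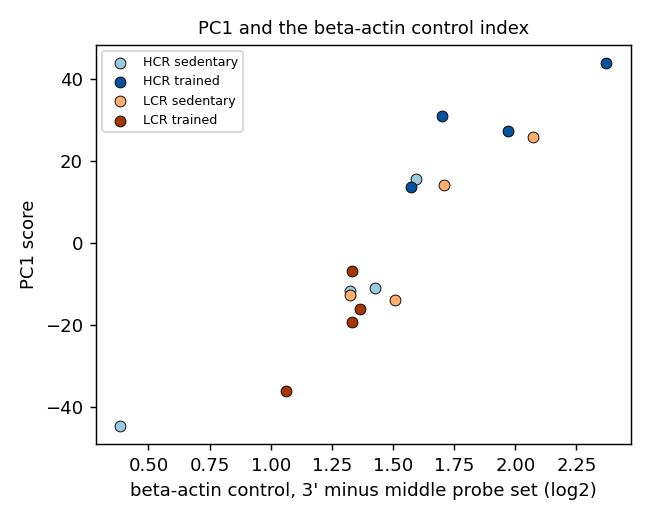
Score of each array on the first principal component (y axis, arbitrary units) against the beta-actin control index (x axis, log2), 1 point per rat, coloured by group. The points rise together, with r = 0.918 over 16 arrays, and the 4 HCR trained arrays lie to the right of the 4 LCR trained ones.

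Training in the HCR line raised Cox7a1, the muscle isoform of a cytochrome c oxidase subunit, by 2.00 log2 units (SE 0.22), a 4.00-fold change, from 6.72 ± 0.21 to 8.72 ± 0.33 (SD, n = 4, adjusted p = 0.00526). Its 4 trained values lay between 8.28 and 8.97 and its 4 sedentary values between 6.52 and 7.01. Myh4 rose by 5.09 (SE 0.87), from 5.68 ± 1.57 to 10.76 ± 2.16 (adjusted p = 0.0475), with all 4 trained values above the 4 sedentary ones, of which the highest was 8.03. The other 3 sedentary values lay below 5.61, the 40th percentile of all probe sets, where the size of a difference is uncertain. The SE pools the spread of all 4 groups, and the Myh4 values of LCR rats lay closer together. They were 4.83 to 5.13 in sedentary and 4.84 to 5.80 in trained LCR rats. In a fit of the HCR arrays alone Myh4 did not pass. Tstd3 rose by 1.38, Atp2b3, a plasma membrane calcium pump, by 1.08, Cmbl by 0.99, Gnb5, a G protein beta subunit, by 0.93, and Sc5d, an enzyme of cholesterol synthesis, by 0.86. Pecr, a peroxisomal enoyl-CoA reductase, rose by 0.84, Egf, a growth factor, by 0.81, Pierce2 by 0.79, Ncdn by 0.77, Tmcc2 by 0.74, and Auh, an enzyme of leucine breakdown, by 0.58. Epc1, a chromatin regulator, fell by 0.55. All of these but Cox7a1 had an adjusted p between 0.0475 and 0.0486. In all, 58 probe sets passed in limma's moderated test, 53 higher and 5 lower, of which 18 carried no single gene symbol and the rest named 40 genes. Another probe set was present for 22 of these genes, and Cox7a1 was not among them. Of those 22, 6 had another probe set at an unadjusted p under 0.05 in the same direction, 0 had one that passed, and in 5, among them Epc1, every other probe set had the opposite sign.

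By gene list, 16 of 29 passed the set test with a preset correlation, 6 higher and 10 lower, and 0 passed with an estimated correlation. The respiratory chain and ATP synthase list was higher, with positive values in 73 of 80 genes, a median of 0.17 and 1 gene past the threshold over all genes, Cox7a1, which was also the only 1 adjusted over the list alone (adjusted p = 0.597 with an estimated correlation). The mitochondrial ribosome list was higher, at a median of 0.20, with 0 of 73 genes past the threshold and 4 higher adjusted over the list alone (adjusted p = 0.513 with an estimated correlation), and Mrpl39 differed by 0.68 (SE 0.14). Its median was 0.13 without HCR sedentary 2. The cytosolic ribosome list was lower in all 42 genes, at a median of -0.22, with 0 past the threshold and 21 lower adjusted over the list alone (adjusted p = 0.427 with an estimated correlation). Rpsa differed by -0.44 and Rps9 by -0.43. The fast fibre list was higher at a median of 0.38 over 17 genes, with Myh4 past the threshold and 7 higher adjusted over the list alone (adjusted p = 0.513 with an estimated correlation). The slow fibre list was lower at a median of -0.60, with 0 of 17 past the threshold by either adjustment (adjusted p = 0.597 with an estimated correlation). The slow fibre mean was -2.19 on the array HCR trained 3 and between 0.14 and 0.21 on the other 3 HCR trained arrays, and the fast fibre mean was 1.98 on HCR trained 3 and between 0.27 and 0.76 on those 3. Without HCR trained 3 the slow fibre median turned to 0.01 and the fast fibre median was 0.15.

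The glycolysis and glycogen list was higher in HCR trained than HCR sedentary rats at a median of 0.38 over 28 genes, with Pgk1 at 0.37 and 1 gene higher adjusted over the list alone (adjusted p = 0.513 with an estimated correlation). The amino acid breakdown list was higher at a median of 0.27 over 25 genes, with Auh past the threshold and 5 higher adjusted over the list alone (adjusted p = 0.527 with an estimated correlation). The citric acid cycle list was higher at a median of 0.15 over 22 genes, with Idh3a at 0.82 and 0 by either adjustment (adjusted p = 0.597 with an estimated correlation). The extracellular matrix list was lower at a median of -0.68 in 33 genes, 0 of them past the threshold by either adjustment, with Col3a1 at -1.17 and Fmod at 1.07 (adjusted p = 0.513 with an estimated correlation). Macrophage and leukocyte markers were lower in all 22 genes, at a median of -0.43 (adjusted p = 0.513 with an estimated correlation), and MHC genes at a median of -0.14 (adjusted p = 0.427 with an estimated correlation). Among the HCR sedentary arrays these 3 lists were highest on HCR sedentary 2, at 1.74, 1.21 and 0.54, and adjusted over the list alone they had 0. Heat shock genes were lower at a median of -0.19 (adjusted p = 0.427 with an estimated correlation), immediate early genes at -0.17 (adjusted p = 0.427 with an estimated correlation) and proteasome genes at -0.14 (adjusted p = 0.513 with an estimated correlation). Satellite cell genes were lower at -0.40 (adjusted p = 0.482 with an estimated correlation) and spindle genes at -0.14 (adjusted p = 0.597 with an estimated correlation). Immediate early genes had 1 higher and 2 lower adjusted over the list alone, satellite cell genes 1 higher, and the heat shock, proteasome and spindle lists 0. Without 1 array or another the medians of 15 of the 16 lists moved by over 1.5 times or turned, the cytosolic ribosome list being the exception. Without HCR trained 3 they were 0.16 for glycolysis, -0.11 for heat shock genes and -0.27 for macrophage markers. Without HCR sedentary 2 the medians were -0.25 for the matrix, -0.05 for macrophage markers, 0.11 for amino acid breakdown, 0.06 for the respiratory chain and 0.02 for the citric acid cycle, as well as -0.11 for immediate early, -0.08 for proteasome, -0.07 for MHC and -0.24 for satellite cell genes, and that of spindle genes turned to 0.01. Larger medians came without HCR sedentary 1 for the citric acid cycle, 0.23, and without HCR sedentary 3 for MHC genes, -0.25. Without both HCR sedentary 2 and HCR trained 3 the macrophage median turned to 0.00546. With the beta-actin index as a covariate 6 lists passed. The lists that did not pass were fatty acid oxidation (adjusted p = 0.358), fatty acid uptake (0.666), mitochondrial biogenesis regulators (0.176), endothelial genes (0.169), antioxidant defence (0.383), protein breakdown (0.358), circadian clock (0.705), calcium handling (0.284), insulin signalling (0.325), adipocyte markers (0.358), blood cell markers (0.595), Schwann cell markers (0.455) and smooth muscle markers (0.434).

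Among genes fixed as of interest, Ppargc1a, a coactivator of mitochondrial biogenesis, differed by 1.20 (SE 0.34, adjusted p = 0.114) at 1 probe set, with another of its probe sets opposite in sign at an unadjusted p under 0.05. Myh7, slow myosin heavy chain, differed by -3.73 (SE 1.17, adjusted p = 0.138) at its probe set of smallest p. On that probe set HCR trained 2 read 6.07, whereas on the brighter Myh7 probe set the same array read 14.27. On the brighter one HCR trained 3 read 12.05, the other 3 HCR trained arrays 14.27 to 14.46 and the HCR sedentary arrays 14.39 to 14.52. The count of probe sets in HCR was 454 without the array HCR sedentary 4, 190 without HCR trained 3, 3 without HCR sedentary 2 or without HCR trained 2, and 1 without HCR sedentary 1, HCR sedentary 3 or HCR trained 4. It was 29 without HCR sedentary 2 and HCR trained 3, which kept 8 of the 58, 1 with the beta-actin index as a covariate, 3 (2 higher and 1 lower) after quantile normalization, 255 (245 higher and 10 lower) after median centring, 1304 (905 higher and 399 lower) with array weights, 21 without dim probe sets, 29 with a variance trend and robust moderation, 2 with the replicate number as a block, 5 with the GAPDH index, 33 for changes of at least 1.5-fold, and 0 in a fit of the 8 HCR arrays alone, and Cox7a1 differed by 1.96 with that covariate and by 2.00 in that fit, without passing.

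**Figure D2:**
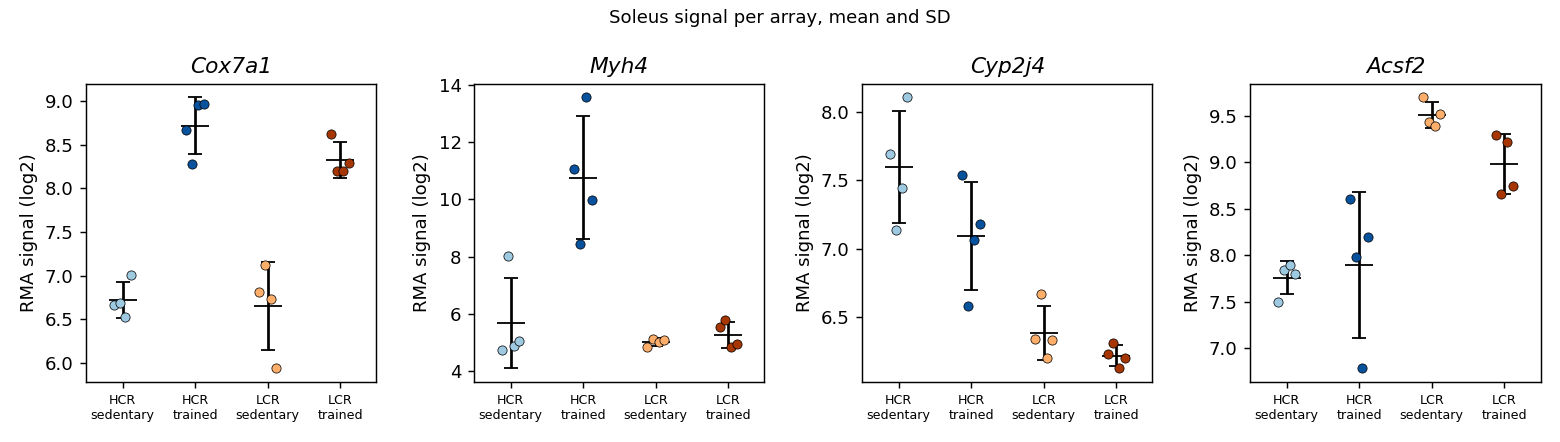
Signal per rat (y axis, RMA log2 value) for Cox7a1, Myh4, Cyp2j4 and Acsf2 in the 4 groups (x axis), 1 point per array, with the group mean and SD as a horizontal mark and bar. Cox7a1 lay between 8.19 and 8.97 in all trained rats and between 5.94 and 7.12 in all sedentary rats, and Myh4 was highest in the HCR trained group.

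Training in the LCR line raised Cox7a1 by 1.67 log2 units (SE 0.22), a 3.19-fold change, from 6.65 ± 0.50 to 8.33 ± 0.20 (SD, n = 4, adjusted p = 0.0465). The 4 trained values, 8.19 to 8.63, lay above the 4 sedentary values, 5.94 to 7.12. It was the single probe set of 31042 that passed, while 3031 had an unadjusted p under 0.05 against 1552 expected by chance. Cd9, a tetraspanin, differed by 1.05 (SE 0.18, adjusted p = 0.248), Dcn, the matrix proteoglycan decorin, by 0.63 (SE 0.13, adjusted p = 0.248), and Mad2l2 by -0.48 (SE 0.07, adjusted p = 0.127), and these did not pass.

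By list, 7 of 29 passed in LCR, all higher, and 0 with an estimated correlation. The extracellular matrix list was higher in 32 of 33 genes at a median of 0.70, with 0 past the threshold and 1 higher adjusted over the list alone, and examples were Dcn and Col4a1 at 0.73 (adjusted p = 0.755 with an estimated correlation). Macrophage and leukocyte markers were higher in 20 of 22 genes at a median of 0.52, with 0 by either adjustment (adjusted p = 0.840 with an estimated correlation). Endothelial genes were higher at a median of 0.15, with Eng at 0.43, Sox18 at 0.49 and 3 higher adjusted over the list alone (adjusted p = 0.755 with an estimated correlation). Smooth muscle and pericyte markers were higher at a median of 0.24 (adjusted p = 0.755 with an estimated correlation), fast fibre genes at 0.16 (adjusted p = 0.889 with an estimated correlation), the respiratory chain list at 0.03 (adjusted p = 0.903 with an estimated correlation) and proteasome genes at 0.05 (adjusted p = 0.889 with an estimated correlation). Adjusted over the list alone, 1 respiratory chain gene, Cox7a1, was higher, and 0 of the smooth muscle, fast fibre and proteasome genes. The matrix mean was 1.20 on the array LCR trained 2 and between -0.29 and 0.39 on the other 3 LCR trained arrays, and without LCR trained 2 the median was 0.45. Without LCR sedentary 4, where the fast fibre mean was -0.86 against -0.45 to -0.04 on the other 3 sedentary arrays, the fast fibre median was 0.09 and the respiratory chain median turned to -0.000409. Over single arrays left out the respiratory chain median reached 0.06, that of fast fibre genes 0.24, and that of proteasome genes ranged from 0.03 without LCR sedentary 1 to 0.10 without LCR sedentary 2. Cox7a1 did not pass when LCR sedentary 1, LCR sedentary 3 or any 1 LCR trained array was left out, with differences of 1.57 to 1.73, and 178 probe sets passed when HCR sedentary 2 and HCR trained 3 were left out of the shared fit, and 321 with array weights. The count was 0 in a fit of the 8 LCR arrays alone, after quantile normalization or median centring, with the replicate number as a block, and with the beta-actin or the GAPDH index as a covariate.

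Over both lines together training raised Cox7a1 by 1.84 (SE 0.15, adjusted p = 0.000173), higher in all 8 trained rats than in any of the 8 sedentary rats. It passed under every alternative tried for this comparison. Cox7a1 had no other probe set with its symbol alone, so the result rests on 1 probe set. The only other probe set to pass has no gene symbol here and rose by 0.49 (SE 0.06, adjusted p = 0.0198). Of the lists 11 passed, 7 higher and 4 lower, and 0 with an estimated correlation. Fast fibre genes were higher in 15 of 17, at a median of 0.34, with 0 past the threshold over all genes and 8 higher adjusted over the list alone (adjusted p = 0.553 with an estimated correlation). Examples that did not pass over all genes were Actn3, fast alpha-actinin, at 2.20 (SE 0.65) and Pvalb, parvalbumin, at 1.98 (SE 0.64), and on the array HCR trained 3 Actn3 read 14.27 and Pvalb 13.80, against at most 11.10 and 9.08 on the other HCR trained arrays. Endothelial genes were higher at a median of 0.13, with 4 of 24 higher adjusted over the list alone, among them Pecam1 at 0.37 (adjusted p = 0.553 with an estimated correlation). The respiratory chain list had positive values in 70 of 80 genes and a median of 0.09 (adjusted p = 0.901 with an estimated correlation). Cytosolic ribosome genes were lower in all 42, at a median of -0.10, with 0 by either adjustment (adjusted p = 0.756 with an estimated correlation). Immediate early genes were lower at a median of -0.11, with 3 lower adjusted over the list alone and Fos at -0.87 (adjusted p = 0.553 with an estimated correlation). Glycolysis genes were higher at 0.19, with 4 higher adjusted over the list alone (adjusted p = 0.756 with an estimated correlation), amino acid breakdown genes at 0.10, with 2 (adjusted p = 0.901 with an estimated correlation), and citric acid cycle genes at 0.07, with 0 (adjusted p = 0.901 with an estimated correlation). Mitochondrial ribosome genes were higher at 0.05 (adjusted p = 0.901 with an estimated correlation), slow fibre genes lower at -0.29 (adjusted p = 0.901 with an estimated correlation) and heat shock genes lower at -0.11 (adjusted p = 0.553 with an estimated correlation), each with 0 by either adjustment. The slow fibre value rested on HCR trained 3, at -2.19, while the other 7 trained arrays lay between 0.09 and 0.22 and the 8 sedentary ones between 0.07 and 0.25, and without that array the median was -0.00212. Without it the medians were also smaller for fast fibre genes, 0.17, glycolysis, 0.10, and heat shock genes, -0.05, and that of endothelial genes was 0.22. The amino acid median turned to -0.00856 without HCR sedentary 2, and those of the citric acid cycle and the respiratory chain were 0.00480 and 0.04. Over single arrays left out the median ranged from -0.18 to -0.07 for immediate early genes and from 0.03 to 0.09 for the mitochondrial ribosome. After quantile normalization 5 probe sets passed, 3 higher and 2 lower, where all had been higher before. The count of probe sets was 72 without HCR trained 3, 50 without LCR sedentary 2, 13 without HCR sedentary 2, 4 without LCR trained 2, 131 without both HCR sedentary 2 and HCR trained 3, and 1148 with array weights. It was 1 without HCR sedentary 1, HCR sedentary 3, HCR trained 2, HCR trained 4, LCR sedentary 3, LCR trained 1, LCR trained 3 or LCR trained 4, with 1 probe set per gene and for changes of at least 1.5-fold, and 245 with both arrays out and the beta-actin index as a covariate.

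The responses of the 2 lines to training were compared by their interaction. In limma 0 probe sets passed, the smallest adjusted p was 0.0801, and 5673 had an unadjusted p under 0.05. Myh4 differed in response by 4.83 (SE 1.23, adjusted p = 0.110), with both LCR means below 5.61. Pmp22, a myelin protein, differed by -1.26 (SE 0.22, adjusted p = 0.0801) at 1 probe set and by -0.22 (adjusted p = 0.650) at its brighter one. C20h22orf15 differed by 0.57, Cnot1, a subunit of the deadenylase complex, by 0.44 and Rnd3 by -1.20, each at adjusted p = 0.0801. Training responses correlated at r = -0.381 across probe sets between the lines, which are not independent replicates, and 22 of 70 ordered splits gave a value at least as large in size (two-sided exact permutation p = 0.314). The lines shared 1 call, Cox7a1, where 0.00171 would be expected of independent lists. Both comparisons used the same estimate of spread per probe set, so their calls are not independent and the expectation is no test. The matrix list gave the lowest median difference in response, -1.39, with 0 of 33 genes past the threshold over all genes and 24 lower and 1 higher adjusted over the list alone (adjusted p = 0.359 with an estimated correlation). Its mean difference, -1.40, was -0.65 without HCR sedentary 2 and LCR trained 2 and -0.25 with the beta-actin index as a covariate. This list test on the interaction was chosen after the data were seen. Without HCR sedentary 4 the count was 185, without HCR trained 3 it was 24, without HCR sedentary 2 and HCR trained 3 together it was 22, and with array weights it was 233.

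**Figure D3:**
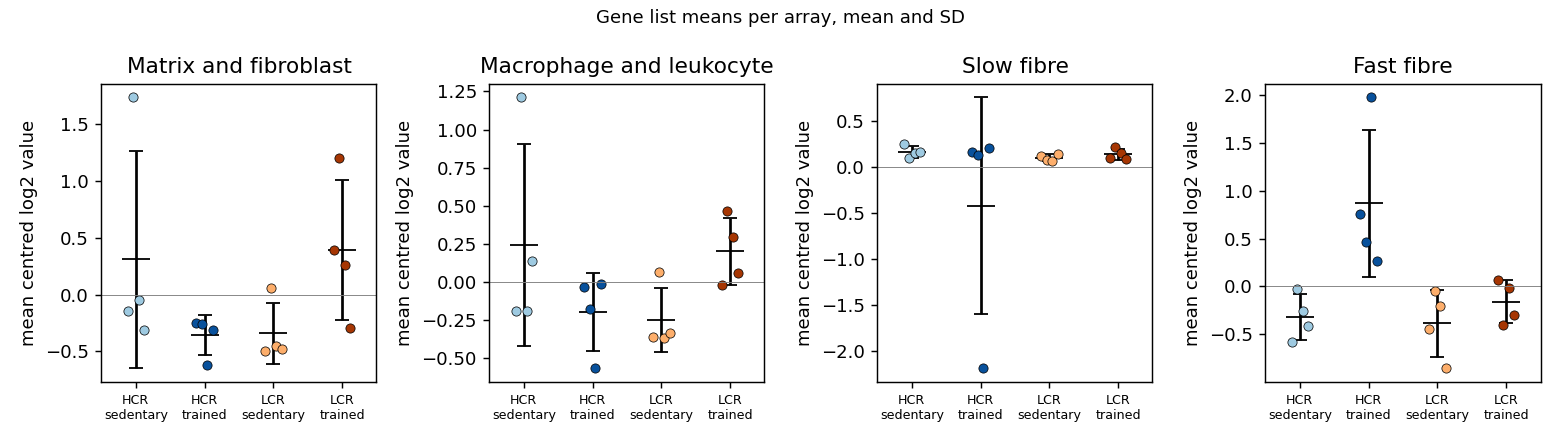
Mean of the centred log2 values of 4 gene lists (y axis) per rat in the 4 groups (x axis), 1 point per array, with the group mean and SD as a horizontal mark and bar. The matrix mean reached 1.74 on 1 HCR sedentary array and 1.20 on 1 LCR trained array, and the slow fibre mean fell to -2.19 on 1 HCR trained array.

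Between sedentary HCR and LCR rats, 3 probe sets passed and all were lower in HCR. None carried a gene symbol here. The one of smallest p differed by -1.25 (SE 0.11, adjusted p = 0.000386), from 7.96 ± 0.13 in LCR to 6.71 ± 0.16 in HCR (SD, n = 4). The remaining ones differed by -0.62 and -0.55, both at adjusted p = 0.0498. An unadjusted p under 0.05 was found for 2598 probe sets. Acsf2, an acyl-CoA synthetase family member, differed by -1.75 (SE 0.28, adjusted p = 0.112), Akr1b10, an aldo-keto reductase, by -1.09 (SE 0.20, adjusted p = 0.185), and Cyp2j4, a cytochrome P450, by 1.21 (SE 0.20, adjusted p = 0.112), and these did not pass.

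Of the lists 12 passed between sedentary rats, 5 higher and 7 lower in HCR, and 0 with an estimated correlation. The matrix list was higher in 31 of 33 genes at a median of 0.68, with Col3a1 at 0.99 (adjusted p = 0.737 with an estimated correlation), and macrophage and leukocyte markers in all 22 at 0.53, with Cd74 at 1.11 (adjusted p = 0.737 with an estimated correlation). The array HCR sedentary 2 stood at 1.74 for the matrix list, while the other 3 HCR sedentary arrays lay between -0.31 and -0.05. Proteasome genes were higher at 0.15 (adjusted p = 0.737 with an estimated correlation), cytosolic ribosome genes in all 42 at 0.12 (adjusted p = 0.737 with an estimated correlation) and spindle genes at 0.13 (adjusted p = 0.737 with an estimated correlation). Lower lists were fatty acid oxidation in all 24 genes at -0.20 (adjusted p = 0.779 with an estimated correlation), amino acid breakdown at -0.25 (adjusted p = 0.737 with an estimated correlation), the citric acid cycle at -0.16 (adjusted p = 0.737 with an estimated correlation), glycolysis at -0.17 (adjusted p = 0.762 with an estimated correlation), the mitochondrial ribosome at -0.12 (adjusted p = 0.737 with an estimated correlation), mitochondrial biogenesis regulators at -0.11 (adjusted p = 0.737 with an estimated correlation) and the respiratory chain at -0.10 (adjusted p = 0.779 with an estimated correlation). Adjusted over the list alone, 1 amino acid breakdown gene, Mccc1 at -0.68, was lower and the other 11 lists had 0 either way. All 12 medians shrank or turned without HCR sedentary 2. The fatty acid oxidation mean was -1.02 on that array, between 0.13 and 0.24 on the other 3 HCR sedentary arrays and between -0.01 and 0.20 in LCR, and without the array its median turned to 0.06. The respiratory chain median turned to 0.00932. Those of the matrix and the macrophage markers were 0.24 and 0.15, the other 5 lower lists lay between -0.09 and -0.03, and the other 3 higher lists between 0.03 and 0.08. Larger medians came without HCR sedentary 1 for fatty acid oxidation, -0.31, and biogenesis regulators, -0.18, and without HCR sedentary 4 for the mitochondrial ribosome, -0.18, and the respiratory chain, -0.16. The beta-actin index was 1.18 in HCR and 1.65 in LCR, and with it as a covariate 3 lists passed. Without HCR sedentary 2 5 lists passed, and without HCR sedentary 2 and HCR trained 3 together 10 probe sets and 6 lists passed, with all 3 probe sets among the 10. With array weights 8 probe sets passed, and 6 with the GAPDH index as a covariate. Only 1 of the 3 passed without dim probe sets, after quantile normalization or median centring, with a variance trend and robust moderation, with the replicate number as a block, and without any 1 HCR sedentary array, LCR sedentary 2 or LCR sedentary 3. A fit of the 8 sedentary arrays alone gave 5 calls, 1 of the 3 among them. With 1 probe set per gene 0 passed, where probe sets without a symbol were not tested.

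Between trained HCR and LCR rats, 116 probe sets passed, 61 higher and 55 lower in HCR. Myh4 was higher by 5.48 (SE 0.87), at 10.76 ± 2.16 in HCR and 5.28 ± 0.46 in LCR (SD, n = 4, adjusted p = 0.0281), with all 4 HCR values above all 4 LCR values. The LCR mean lay below 5.61, so the size of this difference is uncertain, and its SE also pools the spread of the sedentary groups. Gnb5 was higher by 0.89, Phc1, a polycomb protein, by 0.77, Rbpms2 by 0.67, Dok5 by 0.58, Cuedc2 by 0.57, Slc18b1 by 0.53 and Mri1 by 0.51. Ppp2r5c, a phosphatase regulatory subunit, was higher by 0.50, with both of its other probe sets opposite in sign, 1 of them at an unadjusted p under 0.05. Orc4, of the origin recognition complex, was higher by 0.49, Yeats4 by 0.48 and Cbs, cystathionine beta-synthase, by 0.48. Lower in HCR were RT1-Ba, a class II MHC chain, at -2.39 (SE 0.41, adjusted p = 0.0341), Zeb2, a transcriptional repressor, at -2.13, Dpy19l4 at -1.81 (SE 0.24, adjusted p = 0.00818), Tbl1xr1 at -1.62, Rbm5, a splicing factor, at -1.47, C11h21orf91 at -1.46, Fgl2 at -1.38, Ehd4 at -1.31 and Cd9 at -1.10. Rgs4 was at -0.998, Nufip2 at -0.99, Nherf2 at -0.96, Pmp22 at -0.90, Igf1, a growth factor, at -0.84 and Dcn at -0.66. Of the called probe sets, 39 had no single symbol, and the rest named 75 genes.

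Of those 75 genes, 47 had another probe set. Among the 47, another probe set passed in the same direction for 2, RT1-Ba being 1 of them, 12 had another at an unadjusted p under 0.05 in the same direction, and in 14 every other probe set had the opposite sign, among them Ppp2r5c and Pmp22, whose brighter probe set was at 0.02 (adjusted p = 0.965). With only the brightest probe set of each gene tested, 1 gene passed. The beta-actin index was higher by 0.63 log2 units in HCR trained than in LCR trained rats.

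Of the lists 13 passed between trained rats, 2 higher and 11 lower in HCR, and 0 with an estimated correlation. The matrix list was lower in 32 of 33 genes at a median of -0.71, with Dcn past the threshold and also the only 1 adjusted over the list alone (adjusted p = 0.373 with an estimated correlation). Its mean was 1.20 on LCR trained 2, against -0.29 to 0.39 on the other 3 LCR trained arrays, and its median was -0.48 without that array. Macrophage and leukocyte markers were lower at -0.40, with C1qa at -0.92 (adjusted p = 0.474 with an estimated correlation). MHC genes were lower at -0.24, with RT1-Ba past the threshold and 2 lower adjusted over the list alone (adjusted p = 0.373 with an estimated correlation). Heat shock genes were lower at -0.23, with 1 lower adjusted over the list alone and Dnajb1 at -0.51 (adjusted p = 0.185 with an estimated correlation). Slow fibre genes were lower at -0.58 (adjusted p = 0.491 with an estimated correlation), with a mean of -2.19 on HCR trained 3, between 0.14 and 0.21 on the other 3 HCR trained arrays and between 0.09 and 0.22 in LCR, and without HCR trained 3 their median turned to 0.02. Also lower were satellite cell genes at -0.45 (adjusted p = 0.373 with an estimated correlation) and smooth muscle markers at -0.17 (adjusted p = 0.373 with an estimated correlation). Cytosolic ribosome genes were lower at -0.10 (adjusted p = 0.491 with an estimated correlation), proteasome genes at -0.08 (adjusted p = 0.548 with an estimated correlation), immediate early genes at -0.08 (adjusted p = 0.373 with an estimated correlation) and antioxidant genes at -0.04 (adjusted p = 0.373 with an estimated correlation). Without HCR trained 3 the antioxidant median turned to 0.04, and those of smooth muscle, satellite cell and heat shock genes were -0.02, -0.31 and -0.16. The cytosolic ribosome median was -0.05 without LCR trained 2 and that of smooth muscle markers -0.04 without LCR trained 1. Over single arrays left out the median ranged from -0.12 to -0.03 for proteasome genes, lowest in size without HCR trained 2, and from -0.21 to -0.04 for immediate early genes, and the antioxidant median reached -0.08. With the beta-actin index as a covariate 8 lists passed. Mitochondrial ribosome genes were higher at 0.15 (adjusted p = 0.787 with an estimated correlation) and Schwann cell markers at 0.26 (adjusted p = 0.373 with an estimated correlation), although a dimmer probe set of Pmp22 was the 1 that passed, and it was lower. Adjusted over the list alone, satellite cell genes had 1 higher and 3 lower, immediate early genes 1 higher and 2 lower, smooth muscle markers 1 lower, and the other lists of this set without a stated count 0. Fast fibre genes did not pass as a list (adjusted p = 0.0604), but their mean per array was 0.87 ± 0.77 in HCR and -0.16 ± 0.23 in LCR (exact permutation p = 0.0286, adjusted 0.118 over the lists). That p is the smallest that 4 against 4 arrays allow, and other lists, among them the mitochondrial ribosome, gave the same values. For fast fibre genes HCR trained 3 was at 1.98 and the other 3 HCR trained arrays between 0.27 and 0.76. Without HCR trained 3 their HCR mean was 0.50 and the difference 0.66 instead of 1.03.

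The count between trained rats was 255 without HCR trained 3, 229 without HCR trained 1, 21 without HCR trained 2 and 18 without HCR trained 4. It was 9 without LCR trained 1 or LCR trained 3, 15 without LCR trained 2 or LCR trained 4, and 1315 without HCR sedentary 2 and HCR trained 3 together, among them all 116. With array weights it was 3525 (1862 higher and 1663 lower), with the beta-actin index as a covariate 5, and in a fit of the 8 trained arrays alone 836, of which 275 were higher and 561 lower. With a variance trend and robust moderation 87 passed, 33 higher and 54 lower. The count was 77 without dim probe sets, 25 with the replicate number as a block and 15 with the GAPDH index. For changes of at least 1.5-fold it was 69, 19 higher and 50 lower. With both arrays out and the beta-actin index it was 7.

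Over both training states, 27 probe sets differed between the lines, 11 higher and 16 lower in HCR. Cyp2j4 was higher in HCR by 1.04 (SE 0.14, adjusted p = 0.00643), at 7.60 ± 0.41 and 7.09 ± 0.40 in sedentary and trained HCR rats against 6.38 ± 0.20 and 6.22 ± 0.08 in LCR rats (SD, n = 4 each). Dok5 was higher by 0.48, Riok3, a kinase, by 0.29 and Nudt16 by 0.24. Acsf2 was lower in HCR at -1.42 (SE 0.20, adjusted p = 0.00936), with all 8 HCR values, at most 8.61, below all 8 LCR values, at least 8.66. Dpy19l4 was lower at -1.30, Akr1b10 at -0.997 (SE 0.14, adjusted p = 0.00820), Gas6, a ligand of receptor tyrosine kinases, at -0.56 and Cdkn1b, a cyclin-dependent kinase inhibitor, at -0.44. Every other probe set of Riok3 and of Akr1b10 had the opposite sign. Cyp2j4, Acsf2 and Dpy19l4 passed under every alternative tried for this comparison. The smallest adjusted p belonged to the same unnamed probe set that had the smallest p between sedentary rats, here at -1.18 (SE 0.08, adjusted p = 7.83e-06), and another unnamed probe set was higher by 1.15 (SE 0.09, adjusted p = 6.88e-05). In all 17 of the 27 had no single symbol.

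Of the lists 11 passed over both training states, 2 higher and 9 lower in HCR, and 0 with an estimated correlation. Heat shock genes were lower at a median of -0.13, with 1 lower adjusted over the list alone and Hspa2 at -0.86 (adjusted p = 0.311 with an estimated correlation). Fast fibre genes were higher at 0.16, with 2 higher adjusted over the list alone (adjusted p = 0.747 with an estimated correlation), and slow fibre genes lower at -0.28 (adjusted p = 0.747 with an estimated correlation). Antioxidant genes were lower at -0.05, with 1 lower adjusted over the list alone (adjusted p = 0.634 with an estimated correlation). The other lists that passed had 0 by either adjustment. Schwann cell markers were higher at 0.13 (adjusted p = 0.634 with an estimated correlation), and satellite cell genes lower at -0.20 (adjusted p = 0.747 with an estimated correlation), fatty acid oxidation at -0.09 (adjusted p = 0.808 with an estimated correlation), the citric acid cycle at -0.08 (adjusted p = 0.747 with an estimated correlation), protein breakdown at -0.06 (adjusted p = 0.634 with an estimated correlation), amino acid breakdown at -0.05 (adjusted p = 0.747 with an estimated correlation) and the respiratory chain at -0.03 (adjusted p = 0.808 with an estimated correlation). Several of these rested on 1 or 2 arrays. The fatty acid oxidation mean was -1.02 on HCR sedentary 2 and -0.43 on HCR trained 3, between 0.13 and 0.26 on the other 6 HCR arrays and between -0.20 and 0.20 in LCR, and its median turned to 0.06 without HCR sedentary 2 and to 0.13 without both. The slow fibre mean was -2.19 on HCR trained 3, between 0.10 and 0.25 on the other 7 HCR arrays and between 0.07 and 0.22 in LCR, and its median turned to 0.00162 without that array, while those of fast fibre, heat shock and antioxidant genes were 0.05, -0.07 and -0.01. The respiratory chain median turned to 0.02 without HCR sedentary 2, and those of the citric acid cycle and amino acid breakdown were -0.00807 and -0.000413. Other single arrays moved the medians of fast fibre genes to 0.06 (without LCR sedentary 4), satellite cell genes to -0.13 (without LCR trained 2), protein breakdown to -0.04 (without HCR trained 2), fatty acid oxidation to -0.14 (without HCR sedentary 1), the respiratory chain to -0.06 (without HCR sedentary 4) and amino acid breakdown to -0.10 (without LCR trained 2). Without both arrays the amino acid and antioxidant medians turned, to 0.00228 and 0.01. Line differences in sedentary and trained rats correlated at r = -0.217 across probe sets (24 of 70 ordered splits as large in size, two-sided exact permutation p = 0.343). The 2 comparisons shared 1 call, lower in both, where 0.00532 would be expected of independent lists. As they share the estimate of spread per probe set, their calls are not independent and this expectation is no test. The count was 69 without HCR trained 3, 15 without LCR trained 1, 16 without HCR sedentary 1 or HCR trained 4, 17 without HCR trained 2 or LCR trained 3, 103 without HCR sedentary 2 and HCR trained 3 together, and 338 with array weights. It was 18 without dim probe sets, 17 with the replicate number as a block, 3 with 1 probe set per gene, 14 for changes of at least 1.5-fold, 47 with the beta-actin index as a covariate and 50 with both arrays out as well.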

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

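The tests with the beta-actin and GAPDH indices, those about the array HCR trained 3, the fast fibre tests, the test without HCR sedentary 2 and LCR trained 2, the list tests on the interaction and the list medians without single arrays were chosen only after the result was seen, although what the GAPDH tests should show was written before their outcome was known. The tests of other splits were planned.

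Single arrays far from the rest of their group were found in 27 of 200 groups of 4 values, where chance gives about 1 in 20, or 10. The measures overlap and come from the same arrays, so the 27 are not independent and this comparison is no test. The beta-actin index was 1.06 on LCR trained 2, the GAPDH index 0.73 on HCR sedentary 4, and the second component -63.8 on HCR trained 3. HCR trained 2 was not flagged for the control indices, although its GAPDH index, 1.67, was the highest, against at most 0.77 on any other array. Its beta-actin index, 2.37, and its score on the first component, 43.9, were the highest as well. On HCR sedentary 2 the list means stood apart for fatty acid oxidation (-1.02), the citric acid cycle (-0.55), the cytosolic ribosome (0.34), the proteasome (0.31), the extracellular matrix (1.74), amino acid breakdown (-0.63) and proliferation genes (0.64), as did Cpt1b (11.42), Cs (11.67) and Myh4 (8.03). On HCR trained 3 they stood apart for fatty acid oxidation (-0.43), slow fibre genes (-2.19) and Schwann cell markers (-0.0474), as did Lpl (10.52) and Myh7 (12.05). On HCR trained 2 the proteasome mean was -0.22 and that of proliferation genes 0.0647. LCR sedentary 2 stood apart for the matrix (0.0623) and macrophage lists (0.0656), LCR sedentary 1 for Schwann cell markers (0.17) and HCR sedentary 4 for antioxidant genes (0.0777). Single genes apart were Ppargc1a at 7.97 on LCR trained 2, Ucp3 at 8.50 on LCR sedentary 3 and Angptl4 at 6.67 on HCR trained 1.

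The training response of 13 lists differed between the lines by the interaction at the preset correlation, and that of 0 lists with an estimated correlation. Median differences of response, HCR minus LCR, were -1.39 for the matrix (adjusted p = 1.68e-17, or 0.359 with an estimated correlation), -0.95 for macrophage markers (4.03e-10, or 0.359), -0.24 for the cytosolic ribosome (1.72e-11, or 0.359), -0.20 for the proteasome (1.02e-07, or 0.359) and 0.28 for the mitochondrial ribosome (3.23e-06, or 0.610). They were -0.55 for slow fibre genes (0.00449, or 0.675), -0.26 for heat shock genes (0.000952, or 0.359), -0.12 for immediate early genes (0.0298, or 0.610), 0.39 for amino acid breakdown (0.00455, or 0.632), -0.12 for MHC genes (0.000271, or 0.359), -0.22 for smooth muscle markers (0.0135, or 0.359), -0.40 for satellite cell genes (0.00290, or 0.359) and -0.21 for proliferation genes (0.00204, or 0.610). Without HCR trained 3 the slow fibre value turned to 0.04, and without HCR sedentary 2 the values were -0.88 for the matrix, -0.52 for macrophage markers, 0.19 for amino acid breakdown, -0.12 for the proteasome and -0.07 for proliferation genes. Heat shock genes and smooth muscle markers were at -0.11 and -0.13 without HCR trained 3, and over single arrays left out MHC genes ranged from -0.35 to -0.07 and immediate early genes from -0.31 to -0.00385. Control probe sets, which no comparison of genes used, also differed between trained HCR and trained LCR rats, by 0.63 for the beta-actin index and 0.50 for the spike-in mean (exact permutation p = 0.0286, adjusted 0.190, each).

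The calls between trained lines and the calls with training in HCR share the 4 HCR trained arrays and are weighed as 1 pattern. Leaving out HCR trained 3 argued against that array alone as the source, since 98 of 116 calls (0.845) and 53 of 58 (0.914) still passed. Without HCR trained 2, 20 of the 116 and 3 of the 58 still passed, and without HCR trained 4, 17 and 1. Without LCR trained 1, 9 of the 116 did. A fit with fewer arrays also has less power, so these losses do not tell whether a single array was the source. A trend with the beta-actin index stays open and may contribute, since its slope within groups gave the observed sign for 0.888 of the 116 (permutation p = 0.00230 over shuffles within groups) and 0.897 of the 58 (permutation p = 0.00940). For the GAPDH index the shares were 0.681 (permutation p = 0.0868) and 0.552 (permutation p = 0.336), which decides nothing. The index and the groups overlap in part, so line, training and RNA or labelling cannot be separated here for most of these genes, and the biological difference of line and training stays open.

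On HCR trained 3 the slow fibre genes lay below the mean of the other 3 HCR trained arrays by a median of -2.30, and the fast fibre genes above it by a median of 1.003. A fast muscle, alone or mixed, in place of soleus is a candidate explanation, and the values met the cut-offs set for it. Those cut-offs were written after the data were seen, and the fast fibre median met its own narrowly. Myh4 also read 8.43 to 11.08 on the other 3 HCR trained arrays and 8.03 on HCR sedentary 2, against at most 5.80 in LCR rats. The explanation was not tested for those arrays. The control indices gave no sign of RNA degradation particular to this array. Its GAPDH index was 0.482, against 0.67 to 1.67 on the other 3 HCR trained arrays, and its beta-actin index 1.70, against 1.57 to 2.37. The glycolysis list, which holds Gapdh, had a mean of 0.82 on this array. Whether expression altered the GAPDH index was not tested, so degradation is not excluded. A change of fibre type with training in this rat is open and was not tested.

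Matrix genes differed in training response between the lines by a mean of -1.40, although the list did not pass in camera with an estimated correlation (adjusted p = 0.359). Without HCR sedentary 2 and LCR trained 2 the mean was -0.65, a share of 0.467, so these arrays may account for part of it, and with 3 arrays left in those groups the rest cannot be settled. With the GAPDH index as a covariate the mean was -1.42, a ratio of 1.01, which argues against a trend with that index as the whole cause. With the beta-actin index, which was lowest on those 2 arrays (0.384 and 1.06), the mean was -0.25, a ratio of 0.180, so a trend with that index may account for most of it and cannot be parted from the 2 arrays. Differences in the connective tissue of the pieces taken, and a response of the lines, stay open.

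Between trained lines no other split gave as many calls (116, against at most 0 in the other splits, 1 of 35 splits as large). The same held with training in HCR (58, at most 2, 1 of 35) and in LCR (1, at most 0, 1 of 35). The smallest share these splits allow is 1 of 35, and the shares were not adjusted over the comparisons. They therefore do not exclude chance, and the count in LCR was only 1 call, Cox7a1. Another split gave more calls for line over both training states (27, at most 2029, 2 of 100 drawn). This was also so for training over both lines (2, at most 3, 2 of 100). Chance could not be excluded for these counts. The cause of the 2029 calls in 1 other split was not examined. Chance could also not be excluded for sedentary lines (3, at most 110, 2 of 35), and the cause of the 110 was not examined either. For the interaction no call was made, so every split gave as many (0, at most 11, 100 of 100) and nothing about chance follows. For no count of lists could it be excluded: sedentary lines (12, at most 16, 19 of 35), trained lines (13, at most 18, 13 of 35), training in HCR (16, at most 22, 13 of 35), training in LCR (7, at most 13, 18 of 35), line (11, at most 20, 70 of 100) and training (11, at most 21, 70 of 100).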

How the results depend on the processing

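Leaving out HCR sedentary 2 and HCR trained 3 together and the control index covariates were chosen only after the result was seen, and the other alternatives were planned. Of the values that answer a comparison, 219 stayed within 1.5 times of the count or within the spread and 125 moved, and no called value changed direction, although medians of some lists did without single arrays. Of the values of named genes under alternatives, 10465 kept their side of the threshold, 559 lost it and 274 gained it. The 10465 include values of genes that were not called in the comparison and had no call to lose. Of 52 calls of named genes, 45 were lost with the replicate number as a block and 40 with the beta-actin index. With quantile normalization 17 of the 52 were lost, with median centring 7 and with array weights 0. Without HCR trained 4, 44 of 51 were lost, and without HCR trained 3, 4 of 51. The cause of each change was not tested, except that fewer arrays or probe sets entered where they were left out. Signal over background could not be judged from these values, so the precision of dim probe sets is unknown.

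Counts are given in the order sedentary lines, trained lines, training in HCR, training in LCR, interaction, line and training, which were 3, 116, 58, 1, 0, 27 and 2. Array weights gave 8, 3525, 1304, 321, 233, 338 and 1148. Without HCR sedentary 2 and HCR trained 3 they were 10, 1315, 29, 178, 22, 103 and 131, and with the beta-actin index as well 10, 7, 3, 0, 1, 50 and 245. A fit on 8 arrays gave 5, 836, 0 and 0 for the first 4. Leaving out dim probe sets gave 1 for sedentary lines, 77 for trained lines, 21 for training in HCR and 18 for line. Quantile normalization gave 1 for sedentary lines, 3 for training in HCR, 0 in LCR, 1 for the interaction and 5 for training. Median centring gave 1 for sedentary lines, 255 for training in HCR (245 higher, 10 lower), 0 in LCR and 1 for the interaction. A variance trend with robust moderation gave 1 for sedentary lines and 29 for training in HCR. With 1 probe set per gene the counts were 0 for sedentary lines, 1 for trained lines, 3 for line and 1 for training. At least 1.5-fold changes numbered 69 for trained lines, 33 for training in HCR, 14 for line and 1 for training, and 2 for sedentary lines. With the beta-actin index they were 5 for trained lines, 1 for training in HCR, 0 in LCR and 47 for line, and with the GAPDH index 6 for sedentary lines, 15 for trained lines, 5 for training in HCR and 0 in LCR. Cox7a1 passed with training in HCR under all but 3 of 20 alternatives, with adjusted p from 0.000994 to 0.239, and lost its call in LCR under 13 of 20, with adjusted p from 0.00324 to 0.309. Myh4 lost its call under 7 of 20 alternatives with training in HCR (0.000114 to 0.254) and under 7 of 20 between trained lines (0.000234 to 0.0836), and with the beta-actin index it was at 7.09 and 7.24 (0.00622 and 0.00176).

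With the replicate number as a block the counts were 1 for sedentary lines, 25 for trained lines, 2 for training in HCR, 0 in LCR and 17 for line. The 24 same-number pairs correlated between -0.483 and 0.573, with 8 over 0.1. Their mean was 0.0211, against -0.00589 for pairs of different numbers. Of 16 arrays, 7 correlated best with their own number, which was not tested against chance. The numbers were not taken to pair the arrays, although a pairing is not excluded.

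For lists, 0 passed in any of the 6 planned comparisons with an estimated correlation. Line gave 7 lists without dim probe sets. Without HCR sedentary 2 and HCR trained 3, 6 passed for sedentary lines and 10 for training in HCR. With the beta-actin index 3 passed for sedentary lines, 8 for trained lines and 6 for training in HCR, and with both arrays also out 3 for sedentary lines and 11 for training in LCR.

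Leaving out 1 array at a time gave 1 to 2 calls for sedentary lines, 9 to 255 for trained lines, 1 to 454 for training in HCR, 0 to 1 in LCR, 0 to 185 for the interaction, 15 to 69 for line and 1 to 72 for training. Lists ranged from 5 to 13, 11 to 15, 13 to 18, 5 to 8, 7 to 14 for line and 8 to 11 for training. The correlation of line differences ranged from -0.366 to -0.00829 and that of training responses from -0.469 to -0.214. The lowest and highest counts came without LCR trained 1 or 3 and HCR trained 3 for trained lines, without HCR sedentary 1, HCR sedentary 3 or HCR trained 4 and HCR sedentary 4 for training in HCR, and without LCR trained 1 and HCR trained 3 for line.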

Other observations

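Adipocyte markers differed widely between single HCR trained rats, with list means of 1.49 on HCR trained 1 and 1.37 on HCR trained 4 against -0.46 on HCR trained 2 and -0.97 on HCR trained 3. The list did not pass with training in HCR, at a median of 0.43 in 12 genes (adjusted p = 0.358). Hk2, hexokinase of muscle, was at -1.24 (SE 0.32, adjusted p = 0.0766) between trained HCR and trained LCR rats, and Cs, citrate synthase, at 0.41 (SE 0.11, adjusted p = 0.0803), and neither passed. Vegfa, an angiogenic factor, differed by -0.93 (SE 0.28, adjusted p = 0.101) in the same comparison.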
